A study of Mus musculus with 13 samples.

How the data were processed

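Regulatory T cells were sorted as YFP-positive and CD25-positive from CD4 T cells of Foxp3 Cre-YFP mice, per the labels' protocols. RNA-seq held 3 WT and 3 CAT libraries, ATAC-seq 3 WT and 2 CAT libraries, made per the labels from lymph nodes, and TCF1 ChIP-seq 1 WT library from lymph nodes and spleen. The input library was not analysed here. The submitters' processing notes name Bowtie, HOMER, MACS2 and build mm10, with no versions and no role for each tool. The RNA aligner, the annotation and the thresholds of peak calling are not given in the sources used here.

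For RNA-seq the authors deposited, per the file headers, Cuffdiff output with estimated fragment counts per gene and library and with FPKM values that Cuffdiff scaled between libraries. Of the deposited estimated counts 92.5% were whole numbers. The authors' deposited table of the comparison gives group FPKM, a p-value and a q-value per locus, with a smallest p of 5e-05 and no gene names, and was joined to the gene names through the group FPKM (relative tolerance 0.0001). Of 24313 genes with readable names 20377 joined to exactly 1 locus. Of these 20282 were found in the GRCm38.p6 gene table, the assembly behind mm10, and 171 were left out because the locus disagreed. Left out were 25 identifiers turned into dates, at 0.265% to 0.281% of fragments per library, and 13 genes with a failed estimate. The RNA file numbers replicates from 0 where the labels start at 1, and the replicate numbers used here are names only. Unstranded overlap, near-identical copies and pseudogenes can split fragments between genes, and such genes are named as uncertain.

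Each ATAC peak list was called on its own library, as the peak names show. Per the file headers the authors' MACS2 tables give each peak a pileup signal, a fold enrichment ratio over local background, and -log10 p and q values, and these scores are the authors' own. The score columns seem not to belong to the coordinates beside them. Across peaks within a library, which are not independent, the rank correlation of width and pileup was 0.0381 to 0.0547, and between WT libraries overlapping peaks correlated at 0.0958 to 0.133 by score and at 0.865 to 0.872 by width. Scores of single peaks were therefore used only in alternatives, and medians of the score columns only to describe each list, which does not depend on their match to coordinates. The TCF1 list gives positions alone, with every deposited peak 142 base pairs wide and no score. Read depth of the ATAC and ChIP libraries is unknown, although the medians of the authors' pileup signal differ between the genotypes, so no region was tested by signal.

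The design fixed before the data were examined assumed FPKM values and limma. As the files also hold estimated counts, these were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood, TMM factors of 0.978 to 1.03, filter by expression, common biological variation 0.132) in R 4.3.3, and limma 3.58.1 on log2(FPKM + 1), for genes at an FPKM of at least 1 in at least 3 libraries, became an alternative. Changes on that scale understate those of low genes. P-values were adjusted by Benjamini-Hochberg over all tested genes, and also over each list alone. Fixed at the same time were 29 gene lists, tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, the grouping of libraries, the named genes and most alternatives. Named genes were 10 genes given whatever their values, up to 4 members of each list with the largest change among those past the threshold and at an FPKM of at least 1, and the 10 largest increases and 10 largest decreases at an FPKM of at least 5 in either group and above 0 in both. Up to 5 gained regions and 5 lost regions with a TCF1 peak at genes that rose or fell were named in order of the gene's change. Some of the genes that this rule names are not reported here. Other genes and the gene families of the closing part were chosen after their values were seen.

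For genes with 1 to 3 fragments in a genotype a ratio with an exact 95% interval was computed from summed fragments, and for 0 fragments a bound against a floor of 3 fragments over the genotype.

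ATAC peaks of all libraries were joined into regions at an overlap of at least 1 base pair. A region was common with a peak in all 5 libraries, gained with a peak in every CAT and no WT library, and lost in the opposite case. Values per library were compared by two-sided exact permutation of the 10 splits, and shares of regions by Fisher's exact test (scipy 1.17.1), adjusted over 3 tests, with Clopper-Pearson 95% intervals. Genes were joined to regions and TCF1 peaks by the locus in the authors' deposited table extended by 5 kb, and 6 odds ratios were tested by Fisher's exact test. The direct comparison of genes higher with genes lower was added after the data were seen. These loci merge overlapping genes, so for the 10 genes given whatever their values the spans come from the GRCm38 table.

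Alternatives were an adjusted p of 0.01, folds of at least 1.5 and 2, other filters, pseudocounts of 0.1 and 5, quantile normalization, DESeq2 1.42.0 and its size factors, the replicate block, each library left out in turn, the authors' q-value, other peak selections and overlaps, and other loci and covariates (statsmodels 0.14.6). The computations were tested on simulated data. For counts drawn from the real means of 12778 genes, edgeR called 26 of 50 genes changed 1.5-fold, 35 of 50 changed 2-fold, 50 of 50 changed 4-fold and 45 of 50 lowered to 0.25, with 8 false calls. Camera called the 1 list raised and 0 of the others, 4400 of 4400 simulated regions were placed in the right class, and 98 of 100 simulated odds ratio intervals held the true value. The counts were drawn gene by gene, while the real effector and proliferation lists had estimated correlations of 0.337 and 0.354. The simulation therefore does not give camera's error rate on lists of correlated genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.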

Results

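Gene expression, open chromatin and binding of the transcription factor TCF1 were measured in regulatory T cells, the CD4 T cells that depend on Foxp3 and restrain immune responses. The cells were sorted as YFP-positive and CD25-positive from male C57BL/6 mice that carry Cre recombinase and a yellow fluorescent protein under the Foxp3 gene. In the genotype called CAT, Cre removes exon 3 of Ctnnb1, which encodes beta-catenin, and the shortened protein is known to escape degradation. Mice without that allele are called WT. RNA-seq covered 3 WT and 3 CAT libraries, and ATAC-seq, which maps open chromatin by transposase insertion, covered 3 WT and 2 CAT libraries, all at 21 days of age. TCF1 ChIP-seq covered 1 WT library from mice of 10 to 12 weeks, and its input library was not analysed here. The RNA libraries held 24133244 to 31527256 fragments assigned to genes. The TCF1 list held 5876 peaks and the ATAC lists held 27129 to 41197. The labels call the libraries of a genotype separate samples and say nothing more about them, so p-values measure the spread between these samples, part of which may be technical. The series asks how activation of Wnt and beta-catenin signalling changes the regulatory program of these cells.

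Expression differed between the genotypes at 6466 of 13193 tested genes. In CAT cells 3369 genes were higher and 3097 lower (edgeR quasi-likelihood test, adjusted p threshold 0.05, n = 3 per genotype). Among these, Gzma, which encodes the killer cell protease granzyme A, rose from 0.920 ± 0.770 to 2589 ± 1332 CPM (fragment counts scaled to library size; mean ± SD, n = 3). Il10, an anti-inflammatory cytokine, rose from 9.42 ± 1.14 to 139 ± 35.6 CPM, while Nrp1, a surface marker of thymus-derived regulatory T cells, fell from 561 ± 80.7 to 27.9 ± 4.64 CPM. The first principal component held 82.8% of the variance and separated the genotypes. Of the CAT libraries, replicate 3 lay nearest to WT on it, at 49.0 against 65.7 and 63.7. On the second component, with 6.64%, CAT replicate 3 lay at -32.8 while the other CAT libraries lay at 21.3 and 6.93. Fragments fell on 19643 genes in WT replicate 1 and on 19738 in WT replicate 3, against 15750 to 16054 in the other 4 libraries. With WT replicate 2 as the only WT library, edgeR called 1954 genes higher and 1631 lower. The CAT libraries alone then give the spread, and the lone WT library is assumed to vary like them. Of the genes named in the text 9 lost their calls there, with log2 changes of -0.67 for Tcf7, 0.59 for Axin2, 0.21 for Tcf12, -1.71 for Sox4, 0.90 for Pde3b, 1.13 for Pmaip1, -1.10 for Tgfbr3, -1.16 for Cd79b and -1.51 for 5830411N06Rik. No gene called in the comparison of all 6 libraries was called in the opposite direction under any other setting. The balance of the counts did turn in limma on FPKM after quantile normalization, with 1839 genes higher and 2203 lower. Changes named in the text are log2 fold changes of CAT over WT unless stated otherwise. The value after ± is an approximate standard error, the size of the change divided by the square root of edgeR's F statistic.

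**Figure D1:**
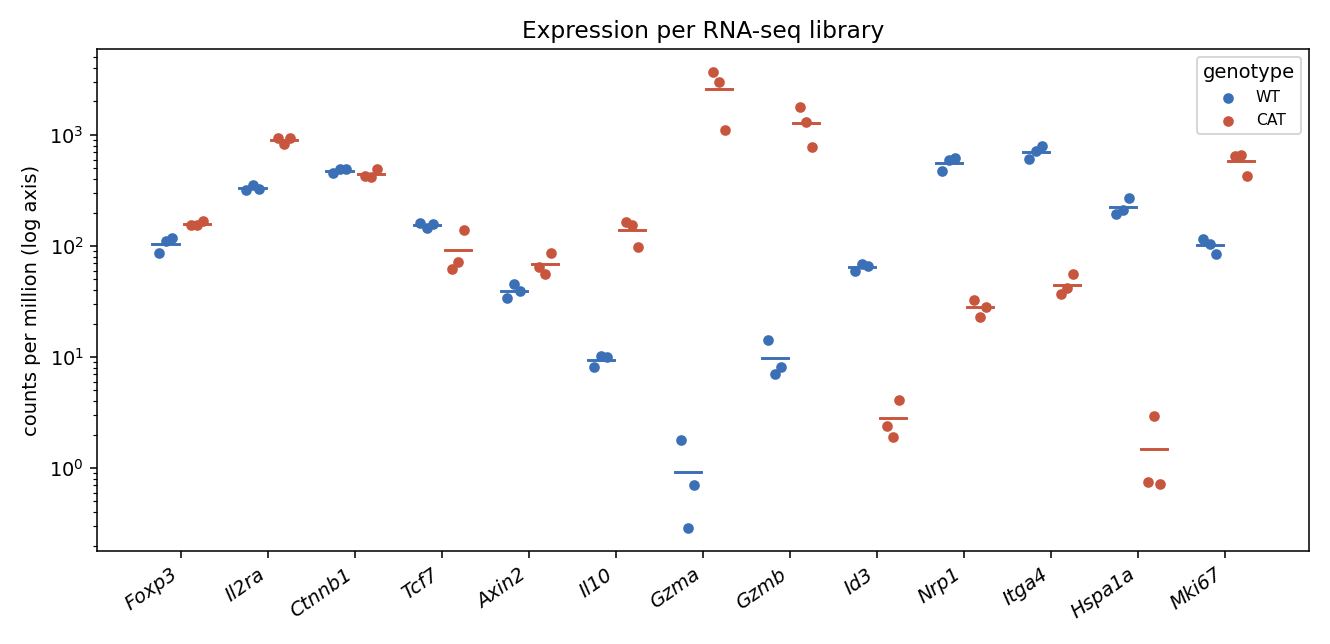
CPM (log axis) of 13 genes in each RNA-seq library. Points are libraries, 3 WT in blue and 3 CAT in red, and lines are the means; Gzma, Gzmb and Il10 stand higher in every CAT library, and Id3, Nrp1, Itga4 and Hspa1a lower.

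Ctnnb1 itself, the gene altered in CAT, had 478 ± 21.7 CPM in WT and 446 ± 41.1 CPM in CAT (log2 change -0.10 ± 0.09, adjusted p = 0.388). This gene total includes fragments outside exon 3 and so does not check the deletion. Of the Wnt and beta-catenin target genes, 15 were tested, of which 5 were higher, 4 lower and 6 not past the threshold. Axin2, a negative regulator that Wnt signalling itself induces, rose by 0.79 ± 0.16 (adjusted p = 0.00312), and the receptor gene Tnfrsf19 rose by 4.14 ± 0.43, or 4.89 without WT replicate 1. Sp5, a transcription factor gene induced by Wnt, had 3 fragments in WT and 416 in CAT, a ratio of 144.6 with a 95% counting interval of 49.15 to 704.2. Its fitted log2 change was 7.03, or 7.89 without WT replicate 3. Jun, an AP-1 subunit gene, changed by -1.30 ± 0.13. Tcf7, which encodes TCF1, was at 155 ± 9.17 CPM in WT and 91.4 ± 42.7 CPM in CAT (log2 change -0.76 ± 0.26, adjusted p = 0.0331). Its spread in CAT came from CAT replicate 3, at 140.3 CPM, while the other CAT libraries had 62.35 and 71.37 CPM. The call of Tcf7 was lost without any one of WT replicates 1 to 3 or CAT replicates 1 and 2 (adjusted p of 0.0693 to 0.110), and in limma on FPKM (0.0531). Sox4, at -1.64 ± 0.54, lost its call without each of the same libraries (adjusted p of 0.0688 to 0.0852) and stood at -2.94 without CAT replicate 3. Lef1 (-0.12 ± 0.10, adjusted p = 0.348) and Myc (-0.24 ± 0.12, adjusted p = 0.119) did not pass the threshold, although without CAT replicate 3 both did (-0.23, adjusted p = 0.037, and -0.35, adjusted p = 0.0194). The list's median was -0.12, its mean 0.64, and camera, which tests a list against all other genes, gave its direction as up with no call (camera adjusted p = 0.689).

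Of 26 Wnt pathway components, 3 were higher and 10 lower. The receptor gene Fzd6 rose by 3.61 ± 0.13, and the ligand gene Wnt10a fell from 4.19 ± 0.176 to 0.0900 ± 0.0783 CPM (log2 change -5.48 ± 0.47). The co-repressor gene Tle1 changed by -1.78 ± 0.13 and Bcl9l, which encodes a beta-catenin cofactor, by -1.38 ± 0.20. Tcf12 is among the 3 higher members, but it encodes the E protein HEB, which is not itself a Wnt pathway component. It rose by 0.32 ± 0.089 (adjusted p = 0.0153), a call lost without WT replicate 3 (adjusted p = 0.0647) and in limma on FPKM (0.0825). The list missed the threshold (camera adjusted p = 0.0910). Among other settings, it passed without WT replicate 1, where its median was -0.25 (adjusted p = 0.0428), and after quantile normalization (0.0467).

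Genes that define regulatory T cells and their suppressive function were mostly higher in CAT. Of 27 tested, 20 rose and 4 fell, or 21 and 4 adjusted over the list alone, with a median of 1.14 (camera adjusted p = 1.16e-11; adjusted p = 0.0574 with an estimated correlation). Foxp3 rose by 0.59 ± 0.11 from 105 ± 16.1 CPM. Gzmb, the gene of granzyme B, rose by 7.06 ± 0.39, Il10 by 3.88 ± 0.20 and Fgl2, a secreted suppressive factor whose locus overlaps another gene, by 3.04 ± 0.21. Il2ra, which encodes CD25, the marker used in the sort, rose by 1.44 ± 0.088. Nrp1 was among the members that fell, at -4.33 ± 0.16. For every other list in the text, counts adjusted over the list alone equal those given unless stated. Other groupings of the RNA libraries, which mix the genotypes, also passed 5 to 12 lists each by camera at the preset correlation. The camera calls of all 14 lists that passed for CAT against WT were lost when the correlation between genes was estimated rather than preset at 0.01, the lowest adjusted p then being 0.0574. By fry, which tests a list without reference to other genes, these lists passed except the interferon response (fry adjusted p = 0.156). Fry also called lists that camera did not. Higher by fry were T helper 17 (adjusted p = 0.00852), activation (0.00737), thymocyte (0.025) and erythroid genes (0.019). In the erythroid list only Alas2 was tested, and by edgeR it did not pass. Lower by fry were Wnt pathway components (adjusted p = 0.0171), follicular (0.0072), TGF-beta (0.0106) and male linked genes (0.0147).

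All 28 effector regulatory T cell genes passed the threshold, 24 higher and 4 lower, with a median of 2.15 (camera adjusted p = 3.89e-22; adjusted p = 0.150 with an estimated correlation). Besides Gzmb and Il10, Klrg1, a receptor of terminally differentiated lymphocytes, rose by 3.87 ± 0.31 and Lgals3, encoding galectin-3, by 3.56 ± 0.30. Of 16 genes of the IL-2 and STAT5 response, 10 rose and 2 fell, or 10 and 3 adjusted over the list alone (camera adjusted p = 2.07e-04; adjusted p = 0.172 with an estimated correlation). Its largest rises were those of the cytokine gene Lif (1.79 ± 0.23), Il2ra, the kinase gene Pim1 (1.41 ± 0.14) and the feedback inhibitor gene Cish (1.40 ± 0.078).

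Genes of the helper T cell programs changed in different ways. In the T helper 1 list 10 of 13 genes rose and none fell (camera adjusted p = 3.62e-08; adjusted p = 0.203 with an estimated correlation). Eomes, a transcription factor of cytotoxic and memory T cells, rose from 1.17 ± 0.153 to 38.0 ± 5.18 CPM, and the receptor gene Il12rb2 (3.72 ± 0.42), the death ligand gene Fasl (2.97 ± 0.20) and the chemokine receptor gene Cxcr3 (2.42 ± 0.19) were higher. In the T helper 2 list 10 of 12 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.98e-06; adjusted p = 0.0574 with an estimated correlation). Il1rl1, which encodes the IL-33 receptor ST2, rose by 3.55 ± 0.20 and Areg, a tissue repair factor, by 3.27 ± 0.33, and Il13 rose by 4.48 ± 0.75 from a low level of 0.0596 CPM, or by 6.01 without WT replicate 3. The T helper 17 list went both ways, with 10 of 20 higher and 6 lower, or 12 and 6 adjusted over the list alone (camera adjusted p = 0.216; 0.0466 without a filter on level). The chemokine gene Ccl20 changed by -5.16 ± 0.58, or -6.63 without CAT replicate 3, while the interleukin 1 receptor gene Il1r1 (5.19 ± 0.27), Tgfb3 (3.89 ± 0.32) and the leukotriene receptor gene Ltb4r1 (3.73 ± 0.32) rose. Il17a had 2 fragments over the WT libraries and 8 over the CAT libraries, a ratio of 4.172 with a counting interval of 0.8327 to 40.33, too few to be tested. Of 12 follicular T cell genes 2 rose and 5 fell, or 3 and 5 adjusted over the list alone. Id3 (-4.51 ± 0.23), Tox (-2.40 ± 0.24) and Bcl6 (-1.81 ± 0.30), all encoding transcription factors, fell, and Icos, a costimulatory receptor, rose by 2.94 ± 0.16. That list's median was 0.027, its mean -0.41 and its camera direction down (camera adjusted p = 0.267), a call made only without CAT replicate 3 among the left-out libraries (adjusted p = 0.0384).

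Proliferation genes were higher in CAT almost without exception, 34 of 35, or 35 adjusted over the list alone, with a median of 1.88 (camera adjusted p = 1.18e-23; adjusted p = 0.150 with an estimated correlation). Ube2c, which targets mitotic cyclins for degradation, rose by 3.58 ± 0.28, the cyclin gene Ccnb1 by 3.02 ± 0.24, the inhibitor of apoptosis gene Birc5 by 2.86 ± 0.22 and the mitotic kinase gene Aurkb by 2.82 ± 0.19. Glycolysis genes rose at 15 of 19 members and fell at 1, or 16 and 1 adjusted over the list alone (camera adjusted p = 9.68e-06; adjusted p = 0.252 with an estimated correlation). Hk2, the first enzyme of the pathway, rose by 2.14 ± 0.19, Tpi1 by 1.57 ± 0.19 and the lactate exporter gene Slc16a3 by 1.20 ± 0.20. Gapdh, at 1.26 ± 0.13, shares reads with many pseudogenes and is uncertain. Of 20 genes of apoptosis and survival 13 rose and 4 fell (camera adjusted p = 0.0158; adjusted p = 0.203 with an estimated correlation), among them, beside Fasl, the death-promoting genes Bid (1.23 ± 0.12) and Pmaip1 (1.15 ± 0.20).

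Of 18 trafficking and gut homing genes 10 rose and 4 fell (camera adjusted p = 0.0349; adjusted p = 0.203 with an estimated correlation), and that call was lost without WT replicate 3 (adjusted p = 0.0604), with WT replicate 2 as the only WT library (0.0862) and in limma on FPKM (0.0949). Itga4, the integrin chain that pairs in gut homing, fell from 702 ± 95.8 to 44.8 ± 9.52 CPM, while the chemokine receptor genes Ccr2 (3.21 ± 0.14), Ccr1 (2.91 ± 0.28) and Ccr10 (3.63 ± 0.47, or 3.03 without CAT replicate 3) rose. Of 31 activation and early response genes 14 rose and 6 fell, or 14 and 7 adjusted over the list alone (camera adjusted p = 0.0900; 0.00707 without a filter on level). Cd69, an early activation marker, rose by 1.91 ± 0.14, and the transcription factor genes Fosl2 (2.25 ± 0.14) and Nfil3 (2.01 ± 0.10) and the early response gene Ier3 (3.00 ± 0.34) were also higher. Of 22 genes of NF-kB and the TNF family 7 rose and 8 fell, with a median of 0.064, a mean of -0.071 and a camera direction of down (camera adjusted p = 0.990). Tnfrsf1b, which encodes TNF receptor 2, rose by 1.96 ± 0.083, while the ligand genes Tnfsf14 (-1.91 ± 0.19), Tnfsf11 (-1.50 ± 0.17) and Lta (-1.05 ± 0.16) fell.

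Naive and lymphoid homing genes fell at 12 of 21 members and rose at 4, with a median of -0.44 (camera adjusted p = 0.117), and the list passed only without CAT replicate 3 (median -0.76, adjusted p = 0.00539). Bach2, a repressor that holds T cells in a resting state, changed by -1.53 ± 0.26 and Ly6c1 by -1.17 ± 0.18. Il7r, the IL-7 receptor gene, went the other way and rose by 2.50 ± 0.15. The phosphodiesterase gene Pde3b was at 1.03 ± 0.35, a call lost without any one of WT replicates 1 to 3 or CAT replicates 1 and 2 (adjusted p of 0.0833 to 0.123) and in limma on FPKM (0.158). Of 15 TGF-beta pathway genes 3 rose and 8 fell (camera adjusted p = 0.0735), a list that passed without WT replicate 1 (adjusted p = 0.0343) and without CAT replicate 3 (0.0223). Itgb8, an integrin chain that activates TGF-beta, changed by -2.48 ± 0.15 and the inhibitor gene Skil by -0.88 ± 0.15, and the protease gene Furin rose by 1.30 ± 0.17. Tgfbr3, at -0.99 ± 0.30, lost its call without WT replicate 2, CAT replicate 1 or CAT replicate 2 (adjusted p of 0.0508 to 0.0715). Interferon response genes fell at 16 of 31 members and rose at 7, with a median of -0.60 (camera adjusted p = 0.0297; adjusted p = 0.727 with an estimated correlation). The antiviral genes Ifi44 (-5.49 ± 0.60), Oasl1 (-4.40 ± 0.42) and Oas2 (-3.40 ± 0.34) and the negative regulator gene Usp18 (-2.62 ± 0.17) fell. The list's call was lost without CAT replicate 3 (adjusted p = 0.199) and in limma on FPKM (0.0742), its median being -0.29 without WT replicate 2. Of 30 chromatin modifier genes 6 rose, 6 fell and 18 did not pass (camera adjusted p = 0.990). Uhrf1 (1.78 ± 0.086), Ezh2 (0.94 ± 0.10) and Satb1 (0.68 ± 0.083) rose and Tet1, a DNA demethylation enzyme gene, changed by -0.96 ± 0.17.

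Heat shock and other genes that respond to tissue dissociation were lower in CAT at 9 of 13 members and higher at 1 (camera adjusted p = 6.14e-04; adjusted p = 0.227 with an estimated correlation). Hspa1a, an inducible heat shock gene, fell from 224 ± 38.2 to 1.48 ± 1.29 CPM (log2 change -7.30 ± 0.40, or -8.25 without CAT replicate 2) and its near-identical copy Hspa1b by a log2 change of -7.08 ± 0.41 (-7.89 without CAT replicate 2). As the copies share sequence, their reads cannot be assigned with certainty. The co-chaperone genes Hsph1 (-1.79 ± 0.26) and Dnajb1 (-1.38 ± 0.12) fell too.

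Markers of other cell types also moved with genotype. Markers of CD8 T and NK cells rose at 10 of 11 tested members (camera adjusted p = 5.17e-08; adjusted p = 0.0574 with an estimated correlation), led by Gzma (11.51 ± 0.67, or 12.4 without WT replicate 1), Gzmk (8.91 ± 0.49), Eomes and Klrc1 (4.18 ± 0.66). These rises stand beside those of Gzmb, Eomes and Fasl in the lists of regulatory and helper T cells. Markers of myeloid and dendritic cells rose at 9 of 13 and fell at 3 (camera adjusted p = 0.00112; adjusted p = 0.302 with an estimated correlation), their median of 1.93 being 1.27 without WT replicate 1 and 1.27 without CAT replicate 2. The MHC class II gene H2-Eb1 (3.65 ± 0.33), the Fc receptor gene Fcgr3 (3.58 ± 0.45) and Ccr2 rose and the lysozyme gene Lyz2 changed by -3.34 ± 0.32. Markers of stromal, endothelial and epithelial cells rose at 4 of 6 and fell at 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00386; adjusted p = 0.150 with an estimated correlation), with Col1a2 (5.15 ± 0.31), Krt18 (3.19 ± 0.31), Epcam (1.67 ± 0.15) and Vim, which T cells also express (2.41 ± 0.16), higher. The list's call was lost in limma on FPKM (adjusted p = 0.0577). Of 7 markers of B and plasma cells Jchain rose by 3.71 ± 0.41, or 4.54 without WT replicate 1, and Cd79b changed by -1.17 ± 0.22, with a list median of -0.44, a mean of 0.10 and a camera direction of down (camera adjusted p = 0.824). Thymocyte markers rose at 2 of 6 members (camera adjusted p = 0.267), Cd8b1 (1.53 ± 0.16) and Cd8a (1.89 ± 0.50). Of 2 tested markers of gamma delta and innate-like T cells (camera adjusted p = 0.459) 5830411N06Rik was at -1.27 ± 0.42, a call lost without WT replicate 2 or 3 or CAT replicate 1 or 2 (adjusted p of 0.0828 to 0.109) and -2.04 without CAT replicate 3. Of the erythroid and platelet markers only Alas2 was tested (0.47 ± 0.25, adjusted p = 0.146), and Hba-a1 had 0 fragments in WT and 43 in CAT, at least 14.95-fold higher against a floor of 3 fragments over the WT libraries. Of 4 male linked genes Kdm5d (-0.57 ± 0.11) and Uty (-0.54 ± 0.085) fell (camera adjusted p = 0.235). The female linked gene Xist was at -0.81 ± 0.41 (adjusted p = 0.131), with 0.968 CPM in WT and 0.548 CPM in CAT.

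**Figure D2:**
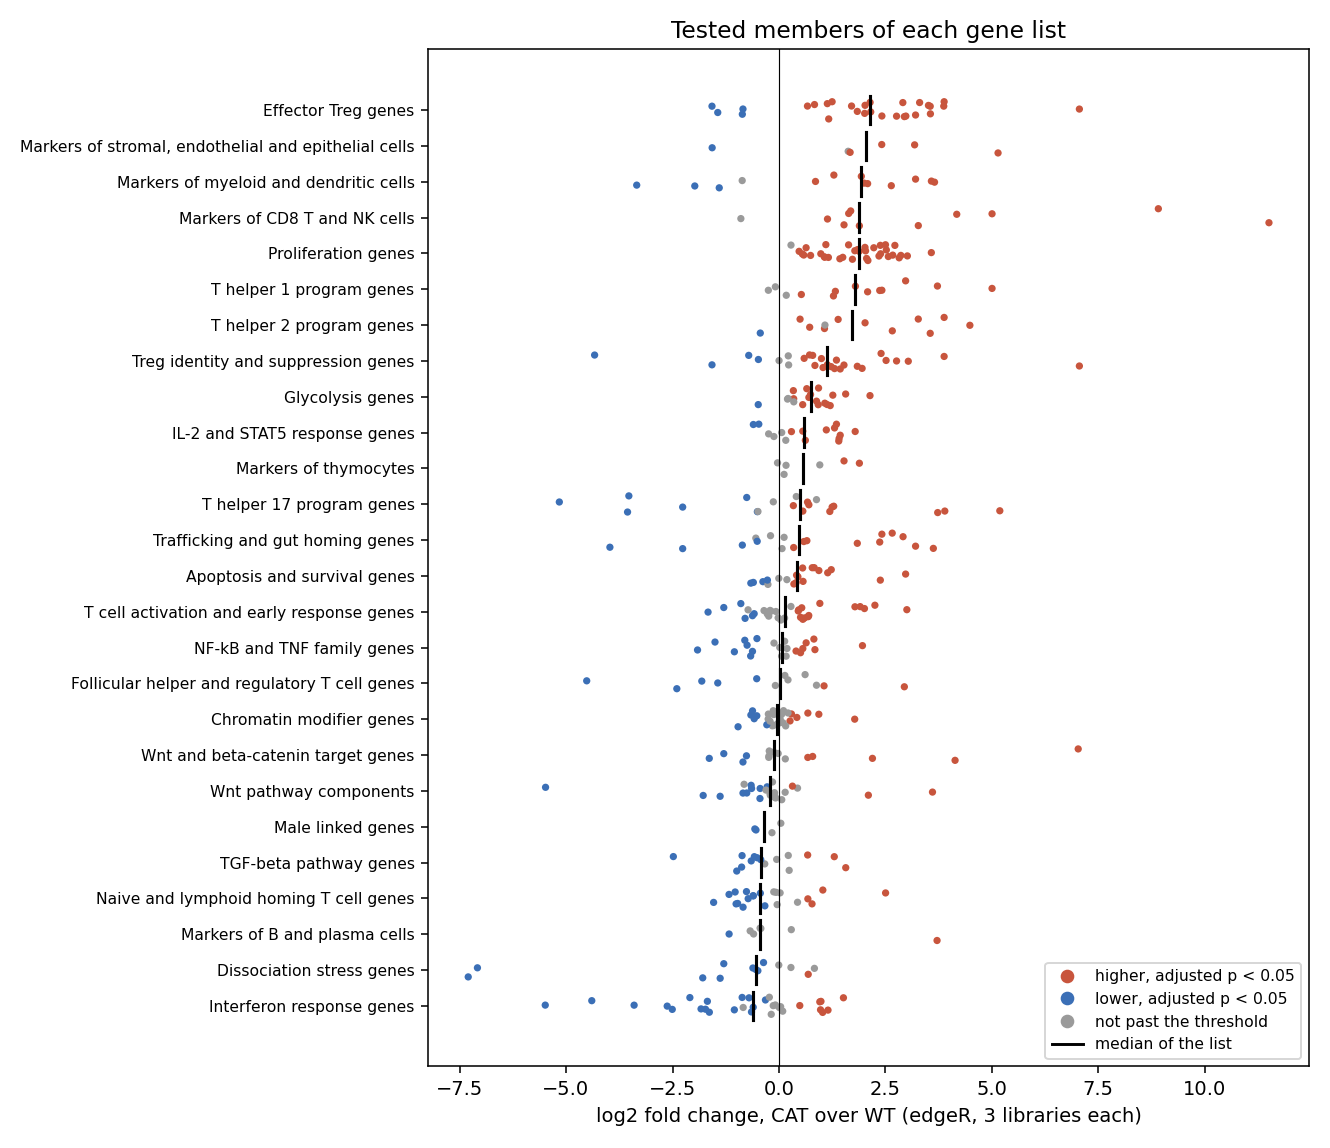
Log2 fold change of CAT over WT (horizontal axis) of every tested gene in 26 of the 29 lists, leaving out those with fewer than 3 tested genes. Points are genes, red where higher and blue where lower by edgeR's adjusted p and grey otherwise, and black bars are list medians, from 2.15 in effector regulatory T cell genes to -0.60 in interferon response genes.

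The 10 largest increases at an FPKM of at least 5 in either group were led by Gzma. Adgrg5, an adhesion receptor gene, rose from 0.339 ± 0.144 to 377 ± 31.8 CPM (log2 change 10.13 ± 0.19, adjusted p = 1.03e-08), and the desmosome gene Dsg2 from 0.243 ± 0.105 to 187 ± 41.5 CPM. Cftr, the chloride channel gene, rose by 9.47 ± 0.45 (8.83 without WT replicate 2 and 10.4 without WT replicate 3) and Cttnbp2 by 9.18 ± 0.43 (8.55 and 10.7 without those libraries), and Gzmk was also among them. The remaining increases rested on 1 to 3 fragments over the WT libraries. The ratio was 2703 (95% counting interval 484.6 to 106800) for Tmem200a, 486.6 (134.3 to 4024) for Cygb, 389.1 (132.8 to 1890) for the fatty acid binding protein gene Fabp4 and 374.1 (127.7 to 1817) for Prss35. All WT fragments of these 4 genes lay in WT replicates 1 and 3, the libraries with fragments on the most genes, so their fold sizes are uncertain. The fitted log2 change of Tmem200a rose to 12.83 without WT replicate 3. Without WT replicate 1 that change went from 8.73 to 11.36 for Cygb, from 8.48 to 9.36 for Fabp4 and from 8.45 to 9.34 for Prss35, and without WT replicate 2 these were 8.14, 7.87 and 7.84. All intervals of counts and shares given here cover counting error only. By the q-value in the authors' deposited table Tmem200a, Cygb, Fabp4, Prss35, Sp5 and Ccl20 did not pass. Beside the heat shock genes Hspa1a and Hspa1b and beside Id3 and Nrp1, the 10 largest decreases were those of Cybb, an NADPH oxidase subunit gene (-5.59 ± 0.17), the sialyltransferase gene St8sia6 (-5.23 ± 0.38, or -6.07 without CAT replicate 3) and Tbc1d4, a regulator of glucose transporter traffic (-5.00 ± 0.22). The others were Gucy1a3, a guanylate cyclase subunit gene (-4.75 ± 0.35, or -5.58 without CAT replicate 3), the glutathione transferase gene Gsta4 (-4.56 ± 0.17) and the netrin gene Ntn4 (-4.12 ± 0.63, or -6.30 without CAT replicate 3). Tbc1d4 fell from 533 ± 26.8 to 16.6 ± 5.48 CPM. The authors' deposited table marks 5984 genes significant, 3177 of them higher and 2807 lower in CAT.

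Open chromatin covered less of the genome in the CAT peak lists. The peaks spanned 19.4 ± 2.27 Mb in WT (SD, n = 3) and 9.22 ± 0.529 Mb in CAT (n = 2; two-sided exact permutation p = 0.1). The median peak was 389 ± 8.39 base pairs wide in WT and 254 base pairs in both CAT libraries (exact permutation p = 0.1). The lists held 41197, 35771 and 33204 peaks in WT and 27129 and 29548 in CAT, 36724 ± 4081 against 28338.5 ± 1710 (exact permutation p = 0.2). With 5 libraries the smallest p is 0.1, so no such test could pass 0.05. Lists of the same genotype shared 0.650 to 0.706 of their combined length and lists of different genotype 0.357 to 0.442. The median pileup that the authors give per peak was 12.85 to 13.8 in the WT lists and 8.34 to 8.95 in the CAT lists. The median fold enrichment went the other way, at 2.64 to 2.76 in WT and 3.52 to 3.65 in CAT. The local background that follows from pileup and fold enrichment had medians of 4.14 to 4.53 in WT and 1.44 to 1.72 in CAT. Peak names follow a different pattern in each genotype, so that separate processing of the genotypes cannot be told apart from genotype in any ATAC comparison.

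**Figure D3:**
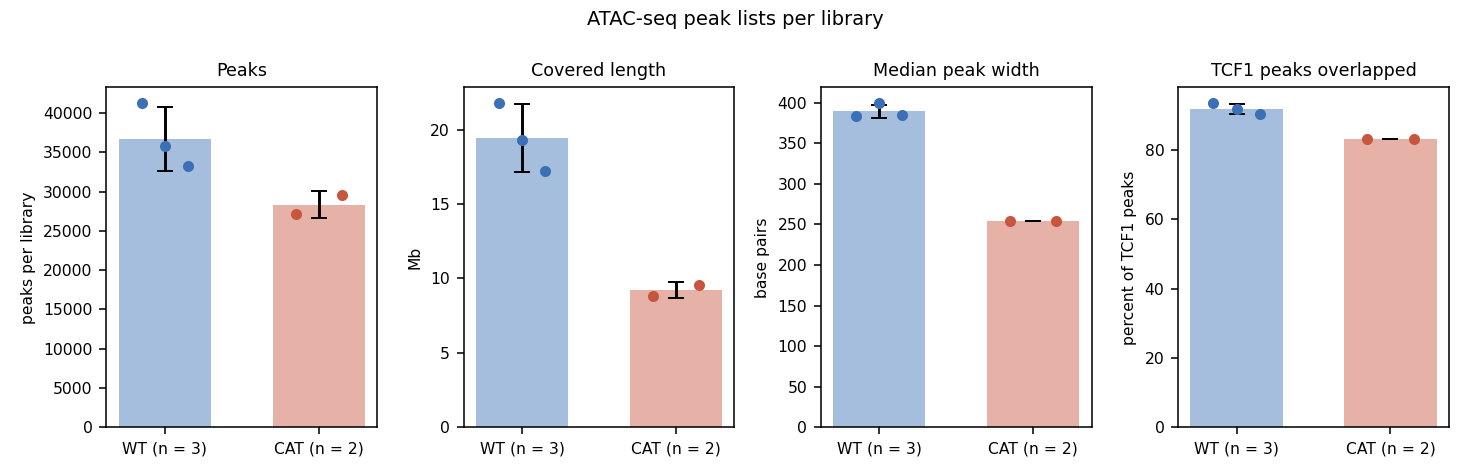
Peaks per library, covered length in megabases, median peak width in base pairs and percent of TCF1 peaks overlapped, for 3 WT and 2 CAT ATAC-seq libraries. Bars are means, error bars SD and points libraries; every CAT library lies below every WT library in all 4 panels.

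Regions were then compared by presence. Of 49014 regions in any library, 19815 held a peak in all 5 libraries, 6054 were lost in CAT (a peak in all 3 WT libraries and in no CAT library), 1929 were gained in CAT (a peak in both CAT libraries and in no WT library) and 21216 were mixed. Over the other 9 ways to set 2 libraries against 3, at most 398 regions were lost from a pair, but up to 2659 were gained, by WT replicates 1 and 2, so the count of gained regions did not exceed that of every other split. With equal numbers of the widest peaks in each library it did, at 2776 against at most 895, and 2775 regions were lost, so that lost regions no longer outnumbered gained ones. In the full lists the gained regions numbered 4068 without CAT replicate 1 and 3114 without CAT replicate 2. The common regions had a median width of 780 base pairs, the lost regions 394 and the gained regions 210.

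At the loci of the genes named in advance, by their spans in the GRCm38 gene table extended by 5 kb, few regions differed. Foxp3 (chromosome X, 7579676 to 7595243, mm10) held 1 common and 1 lost region and 1 TCF1 peak. Myc (chromosome 15, 61985341 to 61990361) held 3 common regions, 1 lost region and 2 TCF1 peaks. Lef1 (chromosome 3, 131110297 to 131224357) held 4 common regions, 1 gained region and 4 TCF1 peaks. Tcf7 (chromosome 11, 52246527 to 52283383) held 3 common regions and 3 TCF1 peaks. Axin2 (chromosome 11, 108917828 to 108950783) held 1 common region and 2 TCF1 peaks, while Ctnnb1 (chromosome 9, 120933400 to 120960507) and Tcf12 (chromosome 9, 71844252 to 72111893) held 1 common region and 1 TCF1 peak each. The loci of Il10 (chromosome 1, 131019845 to 131024970) and Il17a (chromosome 1, 20730905 to 20734496) held no common, gained or lost region and no TCF1 peak.

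Regions open in every library overlapped TCF1 peaks, mapped in WT cells, more often than lost regions. Of the common regions 23.6% (4684, Clopper-Pearson 95% interval 23.0 to 24.2) overlapped a TCF1 peak, of the lost regions 2.38% (144, 2.01 to 2.79) and of the gained regions 0.363% (7, 0.146 to 0.746). Across regions, which are not replicates, the two-sided Fisher's exact test of lost against common regions gave a p below the smallest number the software gives. Lost regions hold no CAT peak by definition, and the CAT lists overlapped 83.0% and 83.1% of the TCF1 peaks. Few of these peaks could thus lie in lost regions, so that test largely reflects the definition. Gained regions hold no WT peak by definition, and each WT list overlapped 90.4% to 93.3% of the TCF1 peaks, so few of these peaks could lie in gained regions. The planned tests of gained against lost (adjusted p = 1.29e-10) and gained against common regions (adjusted p = 3.39e-199) therefore largely restate the definition and say little about TCF1. Common regions of matched width overlapped TCF1 at 10.4% for the widths of gained and 11.4% for those of lost regions. With only the peaks above each library's median score, the shares of gained and lost regions were 12.2% and 11.2%, with the opposite order and no call (adjusted p = 0.399). With equal numbers of the highest scoring peaks they were 2.39% and 2.87%, also with no call (adjusted p = 0.309). Scores of overlapping peaks correlated at only 0.0958 to 0.133 between WT libraries, so these selections say little about strong peaks. Of 5876 TCF1 peaks, each 142 base pairs wide, the WT libraries overlapped 91.8 ± 1.46% (SD, n = 3) and the CAT libraries 83.1 ± 0.0601% (n = 2; exact permutation p = 0.1). In all, 544 TCF1 peaks met an ATAC peak in a WT library and in no CAT library, 28 the reverse and 291 in no library.

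Changed genes were next compared with unchanged ones, among 11256 genes at an FPKM of at least 1 with a locus, of which 2991 were higher, 2696 lower and 5569 not changed. Genes are not replicates, and genes with a merged locus share the same regions, so the p-values of these tests describe the present libraries only. Lost regions were more frequent at genes changed in either direction, at 24.7% of genes higher in CAT (odds ratio 1.47, 95% interval 1.32 to 1.64, two-sided Fisher's exact test, adjusted p = 1.78e-11) and 24.0% of genes lower (1.42, 1.27 to 1.58, adjusted p = 4.61e-09), against 18.2% of unchanged genes. With locus length, number of regions and expression as covariates both odds ratios were smaller, at 1.37 (1.21 to 1.56, adjusted p = 1.88e-06) and 1.16 (1.02 to 1.33, adjusted p = 0.0420). Gained regions lay at 8.12% of genes higher in CAT against 6.52% of unchanged genes (odds ratio 1.27, 1.07 to 1.5, adjusted p = 0.00921), a call lost with the locus not extended (1.18, adjusted p = 0.125) and with the same covariates (1.15, adjusted p = 0.192). At genes lower in CAT gained regions did not pass (1.12, 0.939 to 1.35, adjusted p = 0.207), although without WT replicate 1, CAT replicate 1 or CAT replicate 2 they did (1.20, 1.32 and 1.16; adjusted p of 0.0322, 6.94e-05 and 0.0463), as with genes called at an adjusted p of 0.01 (1.27, adjusted p = 0.0183). Genes higher and genes lower in CAT, compared directly in a test chosen after the data were seen, did not differ past the threshold by two-sided Fisher's exact test for gained (1.13, 0.927 to 1.37, p = 0.233) or lost regions (1.04, 0.921 to 1.17, p = 0.536). TCF1 peaks lay at 40.2% of genes higher in CAT against 46.8% of unchanged genes (odds ratio 0.765, 0.699 to 0.837, adjusted p = 1.03e-08). At genes lower in CAT the share was 44.3% (0.903, 0.823 to 0.991, adjusted p = 0.0386), a call lost with the locus not extended (0.977, adjusted p = 0.663), with all tested genes (0.915, adjusted p = 0.0555) and with GRCm38 coordinates (0.912, adjusted p = 0.0627).

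**Figure D4:**
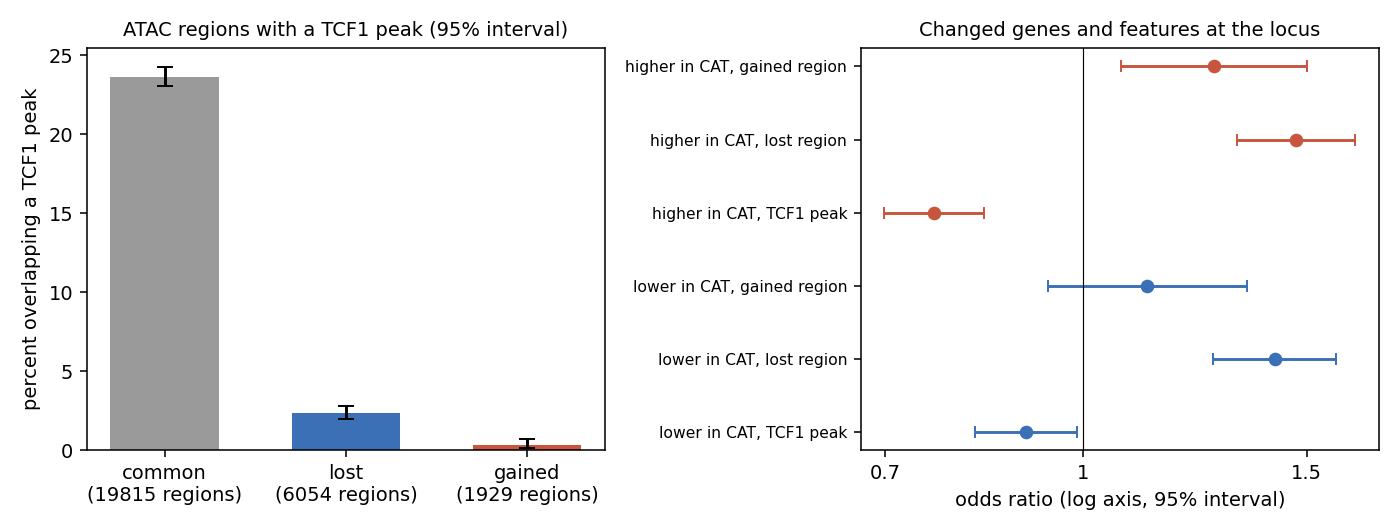
Left, percent of common, lost and gained ATAC regions that overlap a TCF1 peak, with exact 95% binomial intervals (23.6%, 2.38% and 0.363%). By definition lost regions hold no CAT peak and gained regions no WT peak, which limits their shares. Right, odds ratios (log axis) with 95% intervals for changed genes to carry a gained region, a lost region or a TCF1 peak, relative to unchanged genes; points right of the line at 1 stand for a feature more frequent at changed genes.

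Regions were also examined at single loci. Gained regions with a TCF1 peak at a gene higher in CAT were found at 1 gene, Mob3a (log2 change 0.28 ± 0.076, adjusted p = 0.0139), on chromosome 10 from 80700803 to 80700928 (mm10), inside its locus. Among genes lower in CAT, a lost region with a TCF1 peak lay on chromosome 1 from 74806541 to 74807337, outside the span of Wnt10a and within 5 kb of it. Further such regions lay inside the locus of Dtx4, a gene of the Notch pathway (chromosome 19, 12473003 to 12473613; log2 change -2.54 ± 0.18), and inside that of Lrig1, a receptor inhibitor gene (chromosome 6, 94665241 to 94665888; -1.80 ± 0.28), whose locus in the authors' deposited table also holds Slc25a26. The small nucleolar RNA gene Snora7a (-1.73 ± 0.22) shares its locus with Cand2, which overlaps a region on chromosome 6 from 115774022 to 115774973. A region on chromosome 17 from 12677231 to 12677603 lay outside the shared locus of Airn (-2.28 ± 0.22) and Igf2r (-1.70 ± 0.10), which overlap in antisense and whose fragments cannot be told apart without strand. Exons, introns and transcription starts were not in the gene table used here.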

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

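Chosen only after the data were seen were edgeR on counts, the direct comparison of genes higher with genes lower, and the tests with DESeq2, with DESeq2 size factors, with edgeR's replicate block, with WT replicate 2 alone, with the ATAC replicate block, with equal numbers of the widest peaks, with common regions of matched width and with GRCm38 coordinates. The other alternatives were planned, some of them for limma or the authors' q-value and then applied to edgeR. Of the alternatives to main results, 243 kept direction and side of the threshold or stayed within the spread, 6 were weaker, 4 stronger, 44 moved and 1 reversed. Of those to single genes and lists, 3035 stayed, 100 were weaker, 12 stronger, 133 moved and 0 reversed. Of 111 named genes past the threshold, 105 stayed past it in the same direction under each left-out library, and 88 under each of 22 settings with a test. Unless a reason is given, the cause was not tested.

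Genes higher in CAT numbered 2114 at a fold of at least 1.5, 1385 at a fold of at least 2 and 1954 with WT replicate 2 alone, where fewer libraries entered. In limma on FPKM they numbered 2099, 2093 with a pseudocount of 0.1, 2081 with one of 5, 2077 without a filter and 1839 after quantile normalization. Genes lower numbered 2045 at an adjusted p threshold of 0.01, 1673 and 903 at folds of at least 1.5 and 2, 1631 with WT replicate 2 alone, and 1834 in limma, 1815 and 1825 with pseudocounts of 0.1 and 5 and 1805 without a filter. After quantile normalization, which was run in limma on FPKM, the median log2 change was -0.057 and higher genes made up 45.5% of those called. That share was 53.4% in limma without quantile normalization and 52.1% in edgeR. Lists lower numbered 1 in limma, with either other pseudocount or without a filter, and 2 to 4 with 1 library left out.

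Deviations from the group means correlated, across genes, at 0.0996, -0.0475 and 0.0987 for RNA libraries of equal replicate number, and WT replicate 1 correlated best with CAT replicate 2 (0.116). These values show no clear pairing by number. As the numbers are names only, a pairing of the samples cannot be excluded. With the replicate number as a block edgeR called 3349 genes higher and 3035 lower, and limma 2629 and 2311, and in limma with the block the Wnt pathway components passed (median -0.16, adjusted p = 0.0307).

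With an equal number of the widest peaks in each library, the difference in peaks was 0 by construction, in median width -280.0 base pairs and in TCF1 peaks overlapped -5.28 percentage points. There, 2775 regions were lost and 2776 gained, and TCF1 shares were 26.4% of common, 3.24% of lost and 1.80% of gained regions. With equal numbers of the highest scoring peaks 10067 regions were common, 2194 lost and 2347 gained, and the shares were 27.9%, 2.87% and 2.39%, gained minus lost being -0.49 points (adjusted p = 0.309). With peaks above the median score 1209 were common, 1818 lost and 1326 gained, and the shares were 31.8%, 11.2% and 12.2%, gained minus lost reversing to 1.00 point (adjusted p = 0.399), in selections that say little about strong peaks as scores hardly correlate between libraries. With 1 library left out, gained regions ranged from 2004 to 4068 and the TCF1 share of common regions from 21.4% to 23.5%. Merging peaks within a library changed nothing, as none overlap.

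The odds ratio of a gained region at genes higher in CAT was 1.18 with the locus not extended and 1.15 with covariates, and at genes lower 0.881 with covariates, 1.27 at an adjusted p of 0.01 (adjusted p = 0.0183) and 1.15 to 1.32 with 1 library left out. That of a lost region with covariates was 1.37 at genes higher and 1.16 at genes lower. That of a TCF1 peak at genes lower was 0.977 with the locus not extended, 0.915 with all tested genes and 0.912 with GRCm38 coordinates. Motif tests and tests near transcription starts were not run without a genome and strand, nor was a selection of TCF1 peaks by score, as that list holds none. Depth limits genes with few fragments, such as Il17a. In simulated libraries 26 of 50 genes changed 1.5-fold were called, but the changed genes there were all above 1 CPM. They were also a far smaller part of all genes than the called genes are here. That share therefore says nothing about genes with few fragments and is not the power in these data.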

Other observations

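All tests in this part were chosen only after the result they concern was seen. Gene families, defined by the start of the symbol and tested with camera over 17 families, add to the lists. Of 64 histone genes 63 were higher in CAT and none lower, with a median log2 change of 2.03 (camera adjusted p = 8.63e-37; adjusted p = 0.34 with an estimated correlation). Hist2h3c2 rose by 3.69 ± 0.29 and Hist1h3c by 3.33 ± 0.25, although near-identical copies share reads and single members are uncertain. Of 29 kinesin genes 15 rose and 5 fell (adjusted p = 0.00639; adjusted p = 0.34 with an estimated correlation), among them Kif18b (3.02 ± 0.20) and Kif2c (2.88 ± 0.25), motors of the mitotic spindle. Of 17 chemokine receptor genes 10 rose and 2 fell (adjusted p = 0.000218; adjusted p = 0.194 with an estimated correlation), with Cxcr6, a receptor of tissue T cells, at 2.91 ± 0.28 and Ccr6 at -2.26 ± 0.15. Of 8 annexin genes 6 rose (adjusted p = 0.0219; adjusted p = 0.34 with an estimated correlation), Anxa2 by 1.52 ± 0.21. Proteasome subunit genes rose at 18 of 38 members (adjusted p = 0.0332; adjusted p = 0.752 with an estimated correlation) and cytochrome c oxidase genes at 9 of 12 (adjusted p = 0.0441; adjusted p = 0.752 with an estimated correlation).

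Zinc finger genes named Zfp fell at 160 of 319 members and rose at 25, with a median of -0.33 (camera adjusted p = 1.12e-06; adjusted p = 0.34 with an estimated correlation), Zfp72 being at -2.55 ± 0.25. Ribosomal protein genes fell at 35 of 87 and rose at 4, with a median of -0.23 (adjusted p = 0.0054; adjusted p = 0.877 with an estimated correlation). Rps3a1 was at -1.27 ± 0.082, while Rps4l (3.83 ± 0.32) and Rpl39l (2.86 ± 0.38), retrogene relatives of ribosomal genes, rose. The median of each family given a camera p here kept its sign with DESeq2 size factors, in limma on FPKM and after quantile normalization, but not always its size. After quantile normalization the median went from -0.23 to -0.37 for ribosomal proteins and from 0.26 to 0.12 for proteasome subunits. For cytochrome c oxidase it went from 0.43 to 0.21. For chemokine receptors it was 1.10 over 17 genes in edgeR and 1.88 over 13 genes in limma on FPKM. Quantile normalization left it at 1.77 over the same 13 genes. Integrin genes went both ways, 7 of 22 higher and 7 lower, with Itga2, a collagen receptor chain, at 4.30 ± 0.16, Itga4 at -3.97 ± 0.17 and Itgb8 at -2.48 ± 0.15. Of 221 solute carrier genes 59 rose and 52 fell, and Slc43a1, an amino acid transporter gene, rose from 3.51 ± 0.157 to 48.4 ± 0.792 CPM.

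The first pattern weighed is the rise of granzyme genes, with Gzma reaching 2589 ± 1332 CPM in CAT. CD8 T or NK cells passing the sort for YFP and CD25 would bring their other abundant transcripts, yet the largest rise among Nkg7, Ccl5, Cd8a, Cd8b1 and Prf1 was that of Nkg7, from 10.97 to 34.24 CPM, only 0.899% of the rise of Gzma, which argues against such cells as its source. Of the 14 listed CD8 T and NK cell markers 11 were expressed enough to be tested, with Eomes also in the T helper 1 list and Cd8a and Cd8b1 in the thymocyte list. Nkg7, Ccl5, Cd8a, Cd8b1 and Prf1 all rose past the threshold, by 1.14 ± 0.11 (Prf1) to 1.89 ± 0.50 (Cd8a). Klrk1, another marker on that list, went from 10 fragments in WT to 93 in CAT. These rises, small in CPM, were not traced to a cell, so a few such cells are not excluded. Regulatory T cells of the CAT genotype may express the granzymes, and Foxp3 was no lower in the same libraries (log2 change 0.59), but bulk libraries cannot place a transcript in a cell, so this stays open.

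The second pattern is the loss and narrowing of ATAC regions in CAT. A lower number of called peaks is argued against as the whole cause of the losses, since with the same number of the widest peaks in each library 2775 regions were still lost, against at most 508 in the other 9 splits of the 5 libraries. The same lists gained 2776 regions, so the excess of lost over gained regions was gone, and because equal numbers favour such a balance the part of peak number in that excess stays open. Of the common regions 96.7% covered less length in CAT, with a median ratio of 0.571, as a lower signal or a separate run could give. The median pileup was lower in CAT, at 8.34 to 8.95 against 12.85 to 13.8 in WT. The median fold enrichment over local background was higher in CAT, at 3.52 to 3.65 against 2.64 to 2.76. Signal was thus lower in pileup but not in enrichment, and read depth is unknown. These causes cannot be told apart from genotype because the naming of peaks and the genotype split the samples alike. If open chromatin followed expression, lost regions would be rarer at genes higher than at genes lower in CAT, and the odds ratio of 1.04 (95% interval 0.921 to 1.17) includes no difference, so this stays open too.

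The third pattern is the many genes with a few fragments in WT replicates 1 and 3, where 44.4% and 44.8% of 6586 genes silent in the other 4 libraries were detected. Depth is argued against, as the deepest library, WT replicate 2 with 31.5 M fragments, had fragments on only 15750 genes. WT replicates 1 and 3 had fragments on 19643 and 19738 genes. RNA of another cell type would concentrate on its abundant genes, but the top 10 genes held 2.33% and 2.64% of these fragments. Genomic DNA in these libraries may be the source, a hypothesis under which olfactory receptor genes, silent in T cells, are detected about as often as other silent genes, and the differences were -0.942 and -3.11 percentage points. Apart from RNA of another cell type, no biological explanation was tested.

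Other splits of the 6 RNA libraries into 3 and 3 are too few, at 10, for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many as 6466 genes by edgeR, and the highest of the other 9 gave 0, with 29 to 671 genes at an unadjusted p under 0.05 against 7368, edgeR being the one tool run on splits. For lists, 1 of the 10 splits gave as many as the real 14. The other 9 gave 5 to 12 lists each by camera at the preset correlation, while calling 0 genes. Such list calls thus also arose where no gene was called. These splits set unequal numbers of WT and CAT libraries against each other, so they are not free of genotype.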
